A study of Mus musculus with 12 samples.

How the data were processed

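Epidermis was taken from mouse embryos at embryonic day 18.5. Per the labels' protocols, skin was held in 5 mg/ml dispase at 4 C for 3 hours before the epidermis was separated, RNA was extracted with QIAzol and RNeasy columns with DNase I and checked on a Bioanalyser, and Cy3 was used as the label. There were 12 arrays (Illumina MouseWG-6 v2, 1 colour), 3 in each of 4 groups: Psen1/Psen2-null, Rbpj-null, and the wild-type littermates of each line. Groups and replicate numbers were taken from the sample titles. The chip and position of each array are not given in the sources used here, so no chip could be tested as a batch.

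The authors deposited GenomeStudio tables of 45281 probes (gene expression module GSGX 1.6.0, per the file headers). The non-normalized table holds probe intensities from 64.4 to 65945.9, made without background subtraction or normalization per the file headers. The deposited normalized table holds intensities after background subtraction and quantile normalization, per the file headers, and 32.0% of its values are below 0. The detection p-values in both tables were deposited by the authors as GenomeStudio gave them, per the file headers. The deposited series matrix differed from the normalized table in 0 values and was not run separately. Line fragments without a probe, left by line breaks inside annotation text, were dropped (2 from each GenomeStudio file). The number of columns of per-sample values left unused was 0.

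Values were computed from the non-normalized table in R 4.3.3 with limma 3.58.1 and the data.table package (version 1.17.8). The neqc function corrected the background with the detection p-values, added an offset of 16, quantile normalized the arrays and took log2. Probes detected (detection p below 0.05) on at least 3 of the 12 arrays were kept, which were 21851. Names were updated through a reference gene table for 36923 probes: 29586 through the Entrez ID, 2759 through an accession, 2214 through the symbol and 2364 through a synonym. The other 8358 kept the name in the file. For each gene the probe with the highest mean over the 12 arrays was used, which gave 14662 genes, of which 4892 had over 1 detected probe, 12345 had a symbol of the reference and 2767 were known only by a clone, locus or predicted-gene identifier. Coordinates are those of the deposited annotation, whose build is not given in the sources used here. The number of arrays and the signal over background limit the precision: 18832 (41.6%) to 20531 (45.3%) of probes were detected per array.

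The model had 4 group means over the 12 arrays (8 residual degrees of freedom, 3.706 prior degrees of freedom), fitted with lmFit and eBayes. Each null was compared with the wild type of its own line, the difference of these effects was tested as an interaction, and the wild types were compared with each other. Tests were 2-sided and a gene was called at a Benjamini-Hochberg adjusted p below 0.05. An exact permutation test of 3 arrays against 3 cannot give a 2-sided p below 0.1, so single genes were not tested that way. Where a gene was undetected on all 3 arrays of its dimmer group, the fold is given as at least the brighter group's mean over the dimmer group's mean of, per array, the higher of the lowest signal among detected probes and the probe's own signal, on normalized log2 values.

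Gene lists were tested with limma's camera at a preset correlation of 0.01, with the correlation estimated for each list beside it, and with fry, whose p-values are given unadjusted. The estimated correlation was -0.003 for the basal keratinocyte list and -3.9e-05 for the sebaceous gland list. Both lie below the preset value, yet the p-values were higher with it. A higher p with an estimated correlation is therefore not always due to correlated genes. The 26 lists held 630 genes, of which 465 were measured and 8 stood in over 1 list, and p-values were adjusted over all 104 list tests. They covered basal, spinous and granular keratinocytes, keratinocyte stress and alarmins, the inner root sheath and hair shaft, hair follicle signalling, sebaceous gland and lipid synthesis, sterol synthesis, Notch target genes, Notch pathway and gamma-secretase components, Wnt ligands and targets, cell cycle, immediate early and heat shock genes, interferon response and sex-linked transcripts. Markers of other cells were those of Langerhans cells and macrophages, Merkel cells, melanocytes, T and natural killer cells, mast cells and granulocytes, dermal fibroblasts, endothelium, erythroid cells, skeletal muscle, adipocytes, and Schwann cells and neurons.

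The groups, tests, lists, naming rule and other settings listed at the end of this account, except the Xist covariate, the median scaling and the estimated correlation without Rbpj-null 3, were set before the data were examined. The rule named Psen1, Psen2 and Rbpj, and for each null the 10 genes with the largest rise and the 10 with the largest fall among called genes whose groups did not overlap. It named the 5 largest in each direction between the wild types, the 5 shared genes with the largest mean change in each direction, and up to 4 members of each list with the smallest p. Where no gene passed it named those with the smallest p. Other list members, among them Krt5, Krt14, Krt15 and the antigen presentation genes, were named after their values were seen, as were the array differences for a second probe. Clone, locus and predicted-gene identifiers were counted and not named.

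The procedure was tested on simulated data with the array spread of this study. For the Psen comparison over 14662 genes, 42 of 100 genes changed 2-fold and 88 of 100 changed 4-fold were called, 0 with the wrong sign, and 4 of 14442 unchanged genes were called. With no change simulated, 0 genes were called in the Rbpj and in the wild-type comparison. Of 200 simulated lists of 20 genes in the Psen comparison, the 1 shifted by 0.5 log2 units had an adjusted p of 1.23e-09 and 0 unshifted lists were called. Simulated genes varied independently of each other, which real genes do not.

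Alternatives tried were the deposited normalized values (floored at 16), no background correction, no filter on dim probes, a filter that asks for detection on all arrays of 1 group, the mean of all probes, each probe on its own, only the arrays of the comparison, all 6 wild types as 1 control, the trend and robust options, array weights, the replicate number as a block, a minimum change of 2-fold, the nulls against each other, an estimated correlation for lists, and leaving out each array. The Xist signal as a covariate and a median scaling in place of quantile normalization (background-corrected values, with arrays set to a common median of the probes detected on all 12) were added after the data were seen, as was the estimated correlation with Rbpj-null 3 left out.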

Results

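Gene expression was measured in mouse epidermis at embryonic day 18.5 with 12 single-colour bead arrays. Epidermis had been separated from whole skin with dispase. The samples formed 4 groups of 3 replicates. One null group lacked Psen1 and Psen2, the presenilins, which are the catalytic subunits of the gamma-secretase complex that releases the intracellular part of Notch receptors. The other null group lacked Rbpj, the DNA-binding protein through which the released Notch fragment controls transcription. Each null group had its own wild-type littermates, called here the Psen-line and the Rbpj-line wild type. The labels number the replicates but do not say that they were separate animals, so p-values measure the spread between these samples, which may be technical.

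Between 18832 and 20531 of the 45281 probes were detected per array, and mean raw signals ran from 647.2 on Rbpj-null 3 to 923.7 on Rbpj-null 1. Replicates of a group correlated at r = 0.953 to 0.994 across genes, and the number of arrays limits the precision of each value below. Rbpj-null 3 stood apart from the other arrays: its highest correlation with any other array was 0.965, and its position on the second principal component was 63.5 against 6.39 for the next highest array. On that array the granular layer list lay 1.02 and the spinous list 0.73 log2 units below the mean of the 12 arrays (values of -1.02 and -0.73). Rbpj-line wild type 3 was highest on the first component, at 52.7, and its granular list mean was -0.68. The female transcript Xist was detected on 2 of 3 Psen-null arrays and 1 of 3 Psen-line wild-type arrays, with a log2 difference of 2.17 ± 2.09 (SE).

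The targeted genes were read first. The brightest Psen1 probe had a log2 signal of 9.72 ± 0.18 (SD, n = 3) in Psen-null epidermis and 11.55 ± 0.25 in its wild type, so Psen1 fell 3.55-fold (adjusted p = 0.0229, limma). A second detected Psen1 probe read 6.40 ± 0.16 against 8.22 ± 0.12, and the remaining 2 Psen1 probes were undetected on all arrays. Psen2 had no lower signal: its used probe read 8.90 ± 0.08 in the nulls and 8.49 ± 1.13 in the wild type (log2 fold change 0.41 ± 0.45 SE, limma adjusted p = 0.856). The labels do not give the deleted part of either gene, so a Psen2 probe outside it would check nothing. All 3 Rbpj probes were undetected on all 12 arrays, and the Rbpj deletion could therefore not be read from these arrays. In Rbpj-null epidermis Psen1 read 11.17, 11.17 and, on replicate 3, 10.19, against 11.33 ± 0.17 in the Rbpj-line wild type (log2 fold change -0.48 ± 0.26 SE, limma adjusted p = 0.935). The second Psen1 probe read 7.632, 7.661 and, on replicate 3, 6.545, against 8.03 ± 0.20 in that wild type. On both probes all 3 Rbpj-null arrays lay below all 3 Rbpj-line wild-type arrays. On the brightest probe the margin was small, with 11.17 the highest null and 11.18 the lowest wild-type value. In this comparison 8.47% of all genes had groups that did not overlap (10% by chance).

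**Figure D1:**
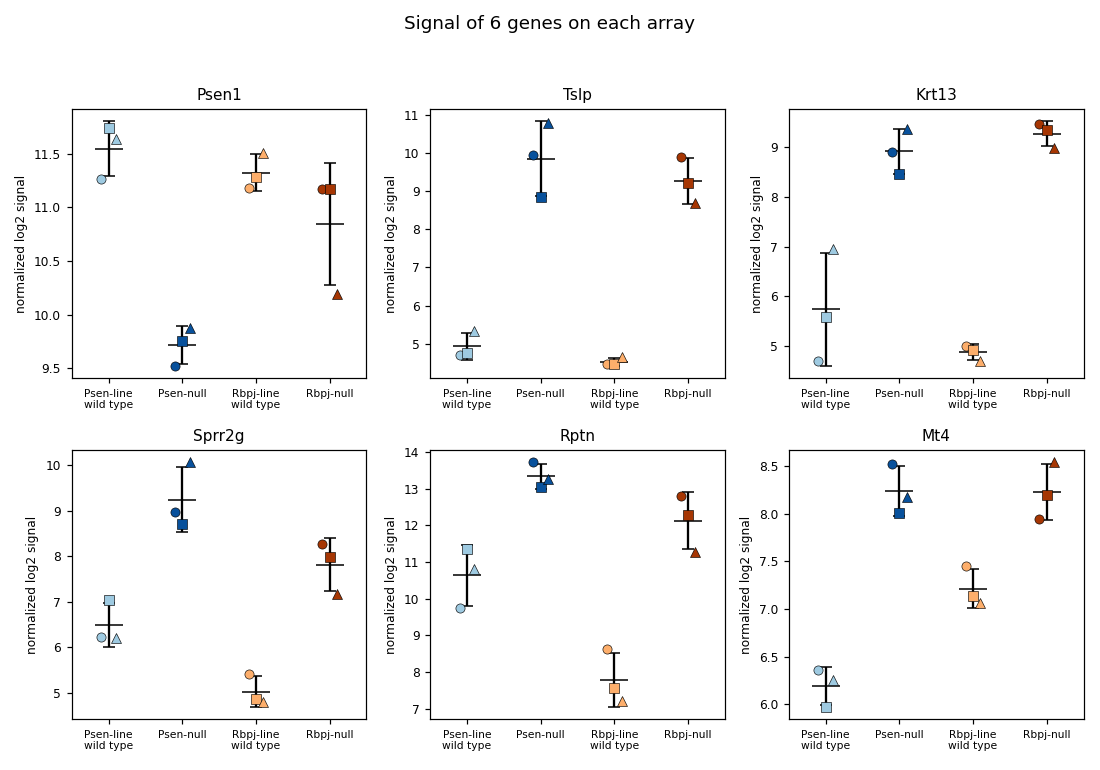
Normalized log2 signal of Psen1, Tslp, Krt13, Sprr2g, Rptn and Mt4 on each of the 12 arrays, by group. Circles, squares and triangles are replicates 1, 2 and 3, and horizontal lines with bars are the mean ± SD (n = 3). Psen1 was lower on all 3 Psen-null arrays (mean 9.72) than on the Psen-line wild-type arrays (mean 11.55), and Tslp was higher on the 3 null arrays than on the 3 wild-type arrays in both lines.

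The first comparison asked which epidermal transcripts changed without both presenilins. The largest rise was in Tslp, an epithelial cytokine that acts on dendritic and T helper cells, at 30.2-fold (log2 fold change 4.92 ± 0.43 SE, n = 3 per group, adjusted p = 0.00137), although only 1 of 3 wild-type arrays detected it. Over the alternatives the log2 fold change of Tslp ran from 3.22 to 5.63, so the size of the fold depends on the processing and the arrays used. The Tslp probe lies at position 32978707 to 32978756 of chromosome 18 in the deposited annotation, whose genome build is not given in the sources used here. Keratin genes that rose were Krt36 by 4.17 ± 0.59 (SE) on the log2 scale (adjusted p = 0.0229), Krt13, a keratin of mucosal epithelia, by 9.01-fold (adjusted p = 0.0229), and the hair keratin Krt32 by 2.87-fold (adjusted p = 0.0406). Of the wild-type arrays, 1 detected Krt36 and 2 detected Krt13. Over the alternatives their log2 fold changes ran from 2.61 to 5.025 for Krt36 and from 2.02 to 3.78 for Krt13. Sprr2g, a small proline-rich protein of the cornified envelope, rose 6.74-fold (log2 fold change 2.75 ± 0.39 SE), and Mt4, a metallothionein of differentiating squamous epithelium, rose 4.13-fold (2.05 ± 0.21 SE, adjusted p = 0.00388). Cyp2b10, a cytochrome P450 enzyme, fell 4.68-fold (adjusted p = 0.0229), and Rhov, a small GTPase, fell 2.59-fold (adjusted p = 0.0473).

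Of 14662 genes tested, 11 rose and 3 fell in Psen-null epidermis at an adjusted p below 0.05. The other genes that rose were Igfbp3 at 8.24-fold, Ms4a10 at 7.12-fold, the tubulin Tubb6 at 3.17-fold (adjusted p = 0.00689), and Ppp2r2b at at least 3.71-fold, being undetected on all 3 wild-type arrays. The eleventh, Lrrn1 (log2 fold change 1.22), lay outside the naming rule and was named after its value was seen. With all detected probes of a gene averaged, all 14 kept their calls. An unadjusted p below 0.05 was reached by 1246 genes, where 733 are expected by chance. In 2686 genes (18.3%) the 3 null values did not overlap the 3 wild-type values, against 10% by chance. Both chance values are averages, and genes are not independent. Splits of the 6 wild-type arrays that mixed the lines gave 4.385% to 33.8% of genes without overlap. The share of 18.3% therefore does not show a broad effect. Tslp and Mt4 kept their calls without any 1 of the 12 arrays (highest adjusted p 0.0168 and 0.0390), although Mt4 lost it with the 6 wild types pooled (0.0613), while each of the other 11 genes that the naming rule gave lost it without at least 3 arrays, with adjusted p up to 0.300 for Rhov. The count of 14 became 2 without Psen-null 1, Psen-null 3 or Psen-line wild type 1, 4 without Psen-line wild type 2 or Rbpj-line wild type 2, 6 without Psen-null 2 or Psen-line wild type 3, and 31 without Rbpj-null 3. It was also 4 without the filter on dim probes, 6 on the 6 arrays of the Psen line alone, 46 with the 6 wild types pooled, and 2124 with array weights, whose estimation stopped before converging at weights from 0.245 to 5.17.

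Genes of the basal keratinocyte list, which holds the hemidesmosome, laminin and integrin genes of the layer on the basement membrane, were shifted up in Psen-null epidermis: 17 of 18 measured members had higher means, with a median log2 change of 0.42 (camera adjusted p = 4.67e-07, adjusted p = 0.0159 with an estimated correlation, and 0.0661 with one when Rbpj-null 3 was left out too). None passed the test over all genes, and 3 rose when adjusted over the list alone: Col7a1, the anchoring-fibril collagen (log2 fold change 0.86), Cdh3 (0.60) and Itga3 (0.60). The abundant keratins of the list had changes of 0.06 for Krt5, -0.05 for Krt14 and 0.32 for Krt15. All 22 measured genes of sterol synthesis had lower means, with a median of -0.36 (camera adjusted p = 3.35e-07, adjusted p = 0.0572 with an estimated correlation). None of the 22 passed over all genes or adjusted over the list alone, and the smallest p-values were those of Mvd (-0.89), Pmvk (-0.74), Lss (-0.68) and Dhcr7 (-0.68). The Wnt list had 22 of 28 members higher (median 0.40, adjusted p = 1.78e-04, adjusted p = 0.115 with an estimated correlation), led by Lef1 (0.84), the transcription factor of the Wnt pathway, Wnt7a (0.89), Wnt10a (0.55) and Kremen2 (0.57). None of its members passed over all genes or adjusted over the list alone.

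The spinous list was shifted down (12 of 15 lower, median -0.34, camera adjusted p = 0.0214, adjusted p = 0.662 with an estimated correlation), and against that direction its member Mt4 rose. Adjusted over the list alone, Mt4 rose and the cyclooxygenase gene Ptgs1 fell (-1.53), and without Psen-line wild type 2 the list's adjusted p was 0.120. Notch target genes were shifted down (8 of 14 lower, median -0.24, and -0.07 with undetected genes at their bound, camera adjusted p = 0.0371, adjusted p = 0.217 with an estimated correlation). Notch3 (-0.87) fell adjusted over the list alone and none passed over all genes. Other values were Hes1 -0.98, Nrarp -0.50 and, in the other direction, Lfng 0.59. Without Psen-null 3 or Psen-line wild type 3 the adjusted p of this list was 0.0898 or 0.114, and 4 other settings at the preset correlation ended the call too (adjusted p from 0.0519 with the deposited normalized values to 0.105 with array weights). The cell cycle list had 30 of 33 members higher (median 0.24, adjusted p = 0.00506, adjusted p = 0.758 with an estimated correlation), with Mcm7 at 0.39 and Mcm4 at 0.40. The hair follicle signalling list had 24 of 33 higher (median 0.22, adjusted p = 0.0231, adjusted p = 0.764 with an estimated correlation), with Tnfrsf19 at 0.52 and Lgr6 at 0.87, and its adjusted p was 0.156 without Psen-null 3, 0.124 without Psen-line wild type 1 and 0.0532 without Psen-line wild type 2. No member of either of these lists passed over all genes or adjusted over the list alone.

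Markers of other cell types also moved with the Psen-null group. Langerhans cell and macrophage genes were lower (18 of 21, median -0.70, and -0.54 with bounds, camera adjusted p = 6.78e-08, adjusted p = 0.217 with an estimated correlation). None passed over all genes, and Cd14 (-1.12) fell adjusted over the list alone. The 3 members with higher means were the antigen presentation genes Cd74 (0.35), H2-Aa (0.18) and H2-Eb1 (0.16). Merkel cell genes were higher (8 of 9, median 0.58, adjusted p = 0.00106, adjusted p = 0.217 with an estimated correlation and 0.0807 with array weights), and the mechanosensory channel gene Piezo2 (0.84) and Insm1 (0.93) rose adjusted over the list alone. Melanocyte genes were higher (9 of 12, median 0.38, adjusted p = 0.0457, adjusted p = 0.714 with an estimated correlation), where Kit (0.88) rose adjusted over the list alone. The melanocyte call ended without Psen-null 2 (adjusted p = 0.0576), Psen-null 3 (0.155), Rbpj-null 1 (0.0532), Rbpj-null 3 (0.0636) or Psen-line wild type 1 (0.201), and under 4 other settings at the preset correlation (from 0.0639 with a stricter detection filter to 0.112 with array weights). With these, 10 of the 26 lists passed in Psen-null epidermis, 1 of them with an estimated correlation and 0 with one when Rbpj-null 3 was left out too. Another split of the same 6 arrays gave 12 lists past the threshold. The unadjusted fry p was 0.317 for the spinous, 0.205 for the cell cycle, 0.209 for the hair follicle signalling and 0.144 for the melanocyte list. For the other lists that passed it ran from 3.71e-06 for basal to 0.0176 for macrophage genes.

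Of the 16 lists that did not pass, keratinocyte stress and alarmins had 13 of 26 members higher (median 0.06, and -0.02 with bounds, adjusted p = 0.242). Tslp rose over all genes, and adjusted over the list alone the wound keratins Krt16 (2.26) and Krt6b (2.55) and the cytokine Il1b (1.52) rose and Serpinb3a (-0.98) fell. The granular layer and cornified envelope list had 37 of 52 lower (median -0.20, adjusted p = 0.0890, 0.00983 without Rbpj-null 3, and adjusted p = 0.736 with an estimated correlation there). Sprr2g rose, and adjusted over the list alone Rptn (2.71), which encodes repetin of the cornified envelope, rose and Sprr2e (-0.72) fell. Sprr, Lce and keratin probes may cross-hybridise within their families. In the inner root sheath and hair shaft list Krt36 and Krt32 rose, and adjusted over the list alone Krt84 (1.69) rose and Krt79 (-1.02) fell (median -0.12, or -0.10 with bounds, mean 0.02, test direction down, adjusted p = 0.766). Notch pathway and gamma-secretase components had a median of 0.05 and a mean of -0.03 (test direction down, adjusted p = 0.855), and Psen1 was the 1 member that fell. The medians of the remaining lists were -0.13 for sebaceous gland (adjusted p = 0.0855, 0.0468 without Rbpj-null 3, and 0.294 with an estimated correlation there), -0.25 for immediate early and heat shock genes (0.0936), -0.19 for interferon response (0.131), and -0.33, or -0.09 with bounds, for T cell and natural killer cell genes (0.130). They were -0.24, or -0.20 with bounds, for endothelium (0.147), -0.43 for dermal fibroblast (0.182), -0.30 for mast cell and granulocyte (0.341), -0.20 for adipocyte (0.392), -0.12 for skeletal muscle (0.491), -0.37 for sex-linked transcripts (0.491), 0.05 for Schwann cell and neuron (0.595, with Plp1 at 0.85 the 1 gene that rose adjusted over the list alone) and 0.15 for erythroid cell (0.698).

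**Figure D2:**
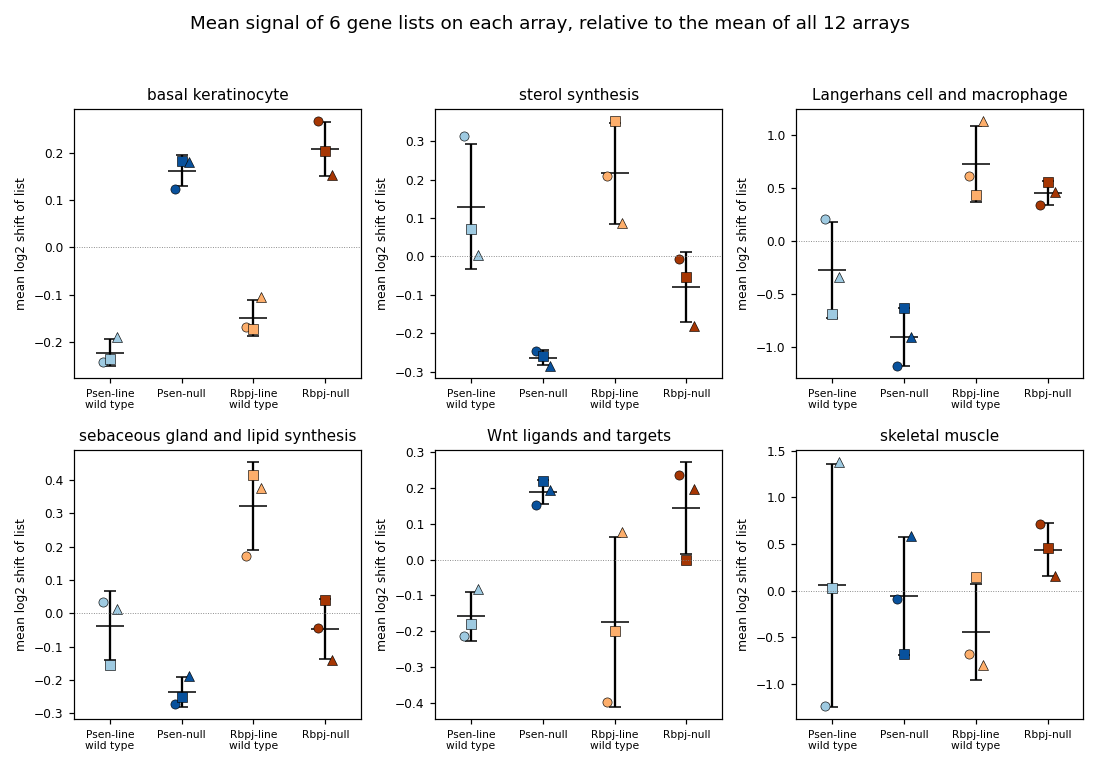
Mean log2 shift of 6 gene lists on each array, relative to the mean of the 12 arrays. Circles, squares and triangles are replicates 1, 2 and 3, and horizontal lines with bars are the mean ± SD (n = 3). All 3 null arrays lay above all 3 wild-type arrays of their line for the basal keratinocyte list, and the skeletal muscle list ranged from -1.23 to 1.38 among the Psen-line wild types.

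The second comparison asked the same of Rbpj-null epidermis. Tslp again had the largest estimate and rose at least 15.5-fold (log2 fold change 4.74 ± 0.43 SE, n = 3 per group, adjusted p = 0.00203), being undetected on all 3 wild-type arrays. Krt13 rose at least 15.4-fold, also from an undetected wild type (adjusted p = 0.00364). Over the alternatives the log2 fold change ran from 2.97 to 5.23 for Tslp and from 2.70 to 5.23 for Krt13. Both bounds therefore hold only for the values as processed here. Rptn rose 20.1-fold (log2 fold change 4.33 ± 0.49 SE, adjusted p = 0.00748), from a level that was 7.16-fold lower in the Rbpj-line than in the Psen-line wild type. Sprr2g rose 6.89-fold (adjusted p = 0.0400), although only 1 of 3 wild-type arrays detected it, and its log2 fold change was 1.47 without background correction (adjusted p = 0.247) against 2.78 with it. Krt32 rose 3.60-fold (adjusted p = 0.0191). Smaller rises were those of Tubb6 at 2.42-fold and the mesothelin-like gene Mslnl at 2.33-fold (both adjusted p = 0.0477). Without background correction the log2 fold change of Mslnl was 0.53 (limma adjusted p = 0.177), against 1.22 with it.

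These 7 genes were all that passed in Rbpj-null epidermis, and 0 fell by limma. An unadjusted p below 0.05 was reached by 820 genes (733 by chance), and 8.47% of genes had groups that did not overlap (10% by chance). Tslp and Krt13 kept their calls without any 1 array (highest adjusted p 0.0176 and 0.0434). Of the 12 leave-outs Rptn lost its call in that of Rbpj-null 1 (adjusted p = 0.0628), and it also lost it on the 6 arrays of the line alone (0.0620) and with the 6 wild types pooled (0.219). Krt32, Sprr2g and Tubb6 kept it in 7, 4 and 1 of the 12 leave-outs, and Mslnl lost its call in each of the 12 leave-outs (adjusted p up to 0.279). The count was 2 without Rbpj-null 1 and 4 without Psen-null 1, Psen-line wild type 1, Rbpj-line wild type 1 or Rbpj-line wild type 3. It was 2 on the 6 arrays of the Rbpj line alone and 11 with each probe tested on its own.

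Basal keratinocyte genes were shifted up here too (15 of 18 higher, median 0.43, camera adjusted p = 4.29e-07, adjusted p = 0.0159 with an estimated correlation, and 0.0661 with one when Rbpj-null 3 was left out too). None passed over all genes, and 5 rose adjusted over the list alone: Col7a1 (0.91), the hemidesmosome genes Itgb4 (0.68), Col17a1 (0.65) and Dst (0.52), and the laminin chain Lamb3 (0.80). Krt5, Krt14 and Krt15 had values of 0.00, -0.09 and 0.14. Sebaceous gland and lipid synthesis genes were shifted down (15 of 17 lower, median -0.37, adjusted p = 5.24e-05, adjusted p = 0.0427 with an estimated correlation, and 0.112 with one when Rbpj-null 3 was left out too), with Elovl3 at -1.14, Pparg at -0.77 and Scd1 at -0.67. Sterol synthesis genes were lower (19 of 22, median -0.32, adjusted p = 2.56e-05, adjusted p = 0.115 with an estimated correlation), with Lss at -0.65, Sc5d at -0.55 and Mvd at -0.54. Wnt genes were higher (25 of 28, median 0.37, adjusted p = 8.49e-05, adjusted p = 0.115 with an estimated correlation), with Wnt7a at 0.63, Wnt10a at 0.47 and Fzd10 at 0.44. In these last 3 lists no member passed over all genes or adjusted over the list alone.

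The spinous list was shifted down (13 of 15 lower, median -0.23, adjusted p = 0.0457, adjusted p = 0.714 with an estimated correlation) while its member Mt4 (1.02) rose adjusted over the list alone. This call rested on single arrays. Its median was -0.04 with the test direction up (adjusted p = 0.845) without Rbpj-null 3, and its adjusted p was 0.0813, 0.101 and 0.0710 without Rbpj-line wild type 1, 2 and 3. With array weights the median was -0.01 (adjusted p = 0.689), with the deposited normalized values the adjusted p was 0.0603 and without the filter on dim probes 0.0926. Inner root sheath and hair shaft genes were lower (26 of 32, median -0.36, adjusted p = 0.0371, adjusted p = 0.767 with an estimated correlation), and the list's Krt32 rose. Without Rbpj-null 1 the adjusted p was 0.756, and without Rbpj-line wild type 3 the median was 0.25 (adjusted p = 0.209). The call also ended under 5 other settings at the preset correlation (adjusted p from 0.0547 with the deposited normalized values to 0.915 with the 6 wild types pooled). The granular list had a median of -0.21 and a mean of 0.06 (test direction down, adjusted p = 0.322), and without Rbpj-null 3 it was shifted up (adjusted p = 4.12e-06, adjusted p = 0.560 with an estimated correlation). Rptn and Sprr2g rose over all genes and Sprr1b (2.51) adjusted over the list alone. Stress and alarmin genes had a median of -0.07 and a mean of 0.18 (test direction up), where Tslp rose and Krt16 (1.51) rose adjusted over the list alone. Notch target genes had 9 of 14 members lower (median -0.06, adjusted p = 0.491), with Hes1 at -0.54, Hey1 at 0.99 and Nrarp at -0.15.

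Among other cell types, all 17 measured skeletal muscle genes were higher in Rbpj-null epidermis (median 0.74, and 0.71 with bounds, adjusted p = 2.46e-05, adjusted p = 0.630 with an estimated correlation), with Tnnc2 at 2.35 ± 1.08 (SE) and none passing over all genes or adjusted over the list alone. Langerhans cell and macrophage genes were lower (17 of 21, median -0.59, adjusted p = 3.55e-05, adjusted p = 0.360 with an estimated correlation). Cd14 (-0.87) and Csf1r (-0.93) fell adjusted over the list alone, and the call ended without Rbpj-line wild type 3 (adjusted p = 0.0765). The 4 members with higher means were the antigen presentation genes H2-Ab1 (1.68), Cd74 (1.39), H2-Eb1 (0.83) and H2-Aa (0.77), none of which passed. With the 6 wild types pooled as 1 control the direction turned (median 0.16, adjusted p = 0.773). Merkel cell genes were higher (6 of 9, median 0.43, adjusted p = 0.00550, adjusted p = 0.332 with an estimated correlation), and Piezo2 (0.75) rose adjusted over the list alone. In all, 9 lists passed, 2 of them with an estimated correlation and 0 with one when Rbpj-null 3 was left out too, and the adjusted p of the other 17 ran from 0.0689 for hair follicle signalling to 0.975 for sex-linked transcripts. Another split of the same 6 arrays gave 10 lists past the threshold. The unadjusted fry p was 0.602 for the hair shaft, 0.359 for the spinous, 0.162 for the skeletal muscle and 0.0785 for the macrophage list. For the other lists that passed it ran from 3.17e-06 for basal to 0.0190 for Merkel cell genes.

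The effects of the deletions were then set side by side. Tslp, Krt13, Sprr2g, Krt32 and Tubb6 rose in both nulls, 5 genes where independent lists of these sizes would share 0.0053. The lists are not independent, since both tests used the same estimate of each gene's spread, taken over all arrays. The value of 0.0053 is therefore not a chance expectation for this overlap. With each line fitted on its own arrays, 6 genes were called in Psen-null and 2 in Rbpj-null epidermis, and 1 was shared. The 16 genes called in either null had the same sign in both. Igfbp3, called in Psen-null epidermis only, had a log2 fold change of 2.88 ± 0.44 (SE) in Rbpj-null epidermis (adjusted p = 0.0598), and Ms4a10 had 2.35 ± 0.38 (adjusted p = 0.0836). Rptn, called in Rbpj-null epidermis only, was 6.52-fold higher in Psen-null epidermis (adjusted p = 0.0776). Across all genes the fold changes correlated at r = 0.523 (Spearman's rho 0.477, covariance 0.0633), and 66.6% had the same sign, although genes are not independent replicates. The fold changes of the comparisons share no arrays, unlike the spread used to test them. The r was 0.150 with array weights and ran from 0.331 to 0.548 when single arrays were left out, and the number of shared genes ran from 1 to 7.

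**Figure D3:**
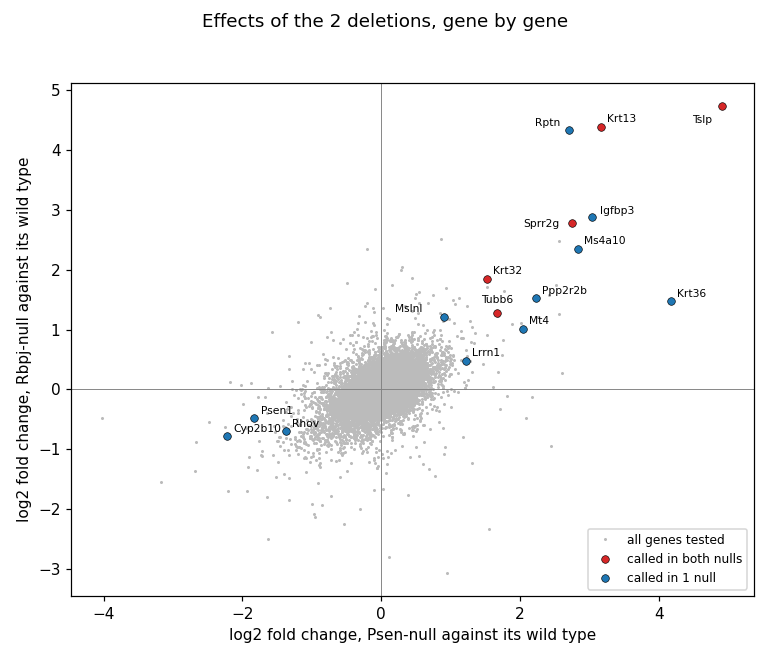
Log2 fold change of each of the 14662 genes in Psen-null (x axis) and Rbpj-null epidermis (y axis), each against its own wild type. Red points are the 5 genes called in both nulls and blue points the 11 called in 1. All 16 lie in the upper right or lower left part of the plot, where both changes have the same sign, and r across all genes was 0.523.

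Whether the effects differed was tested directly. No gene passed (0 by limma, with 243 genes at an unadjusted p below 0.05 and 733 expected). With fewer small p-values than expected the test may be conservative, so 0 genes does not show that the effects are equal. The smallest limma adjusted p over all genes was 0.133, for a gene known only by a clone, locus or predicted-gene identifier. Among named genes the smallest p-values were those of Gch1 (log2 difference 4.00), Pla2g7 (1.01), Ntrk2 (-0.92), Dlgap5 (2.24) and Fzd1 (1.05), all with adjusted p = 0.9998 and so not passing. Mt4 differed by 1.03 (95% interval 0.39 to 1.67) and Cyp2b10 by -1.44 (-2.40 to -0.48), neither past the adjusted threshold. Tslp and Krt36 were undetected on most wild-type arrays, so the size of their effects was not compared between the nulls, and Ntrk2 was detected on 0 of 3 arrays in 2 of the groups and Fzd1 on 0 of 3 in 1. The count was 1 with the deposited normalized values or without Rbpj-null 2. Setting the nulls against each other without their wild types gave 121 genes, a contrast that also holds what differs between the lines.

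At the level of lists, skeletal muscle genes had a lower effect in Psen-null than in Rbpj-null epidermis (16 of 17 lower, median -1.07, camera adjusted p = 1.61e-06, adjusted p = 0.537 with an estimated correlation), and the call ended without Psen-line wild type 3 (adjusted p = 0.0624), with the 6 wild types pooled (median -0.39, adjusted p = 0.0711) and with the nulls set against each other (0.104). Interferon response genes differed by a median of -0.17 (11 of 15 lower, adjusted p = 0.0238, adjusted p = 0.360 with an estimated correlation), with Bst2 at -1.08 and Stat1 at -0.49. That call ended without Psen-null 3 (0.103), Rbpj-null 3 (0.170), Psen-line wild type 1 (0.156) or Rbpj-line wild type 2 (0.0573), without the filter on dim probes (0.191) and with array weights (0.347). All 8 endothelium genes had a lower effect (median -0.41, adjusted p = 0.0448, adjusted p = 0.714 with an estimated correlation), with Eng at -0.71 and Sox18 at -0.60. The endothelium call ended without Psen-null 3 (0.155), Rbpj-null 3 (0.357), Rbpj-line wild type 1 (0.258) or Rbpj-line wild type 2 (0.110), and without Psen-line wild type 3 the test direction turned (median -0.11, adjusted p = 0.850). It ended under 5 other settings at the preset correlation too (adjusted p from 0.0959 with the Xist covariate to 0.770 with the nulls set against each other). In none of the 3 lists did a member pass over all genes or adjusted over the list alone. Their unadjusted fry p was 0.257 for skeletal muscle, 0.132 for interferon response and 0.428 for endothelium. Without Rbpj-null 3 the endothelium and interferon calls ended and 6 other lists passed: granular (adjusted p = 1.05e-10), spinous (0.0120), immediate early and heat shock (0.0301) and sterol synthesis (0.0482) in the direction down, and cell cycle (0.00765) and hair shaft (0.0135) in the direction up. With an estimated correlation and without that array 0 lists passed for the difference (adjusted p from 0.294 for spinous to 0.736 for hair shaft among these 6, and 0.382 for granular). In 3 lists that did not pass, the sign of the median differed from the test: erythroid (-0.09), Notch pathway (0.01, mean -0.11) and Schwann cell and neuron (-0.09).

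The wild-type groups were compared to see what differed between the lines without either deletion. Zcchc9, detected on 2 of 3 Rbpj-line arrays, was 19.0-fold higher in the Psen line (log2 difference 4.25 ± 0.55 SE, n = 3 per group, adjusted p = 0.00643), Fgfr1op2 13.4-fold and Tomm22, a subunit of the mitochondrial import channel, 10.1-fold. Agpat5 and Rptn were 7.44-fold and 7.16-fold higher. Arl5a was 26.1-fold lower in the Psen line (-4.70 ± 0.26 SE, adjusted p = 3.59e-06), the lipase gene Pnpla3 21.3-fold lower, Gpr137b-ps at least 12.4-fold lower, being undetected in the Psen line, the proteasome gene Psmd8 9.59-fold lower and Obi1 7.14-fold lower. A second detected probe of Tomm22 differed by 0.34 and one of Fgfr1op2 by 0.62, against 3.33 and 3.74 for the probes used. A second probe of Rptn differed by 2.71, and 2 other probes of Arl5a by a mean of -5.53.

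Of the 14662 genes, 14 were higher and 57 lower in the Psen line, 11 of the 71 being known only by a clone, locus or predicted-gene identifier. An unadjusted p below 0.05 was reached by 844 genes (733 by chance), and the groups did not overlap in 9.68% of genes (10% by chance). Of the 10 genes named above, 8 kept their calls without any 1 array (Agpat5 lost it on the 6 wild-type arrays alone, adjusted p = 0.0695), Obi1 lost it without Psen-line wild type 3, Rbpj-line wild type 1 or Rbpj-line wild type 2 (adjusted p up to 0.0597), and Rptn lost it without any 1 of 8 arrays (up to 0.136). The count of 71 became 18 without Rbpj-line wild type 1, 22 without Psen-line wild type 3, 28 without Rbpj-line wild type 2, 35 without Psen-line wild type 2, 36 without Rbpj-line wild type 3 or Psen-null 1, 42 without Psen-null 2 and 44 without Psen-null 3. It was 35 without background correction, 38 without the filter on dim probes and 21 on the 6 wild-type arrays alone.

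Macrophage genes were lower in the Psen-line wild type (18 of 21, median -1.10, camera adjusted p = 3.32e-17, adjusted p = 0.0572 with an estimated correlation). Adgre1, a surface receptor gene of macrophages (-2.23), Csf1r (-1.72), Cx3cr1 (-1.94) and Mrc1 (-2.20) passed over all genes, and 12 members did adjusted over the list alone. The 3 members with higher means were H2-Ab1 (1.52), H2-Aa (1.49) and H2-Eb1. Adgre1 kept its call without any 1 array, Csf1r lost it without Psen-line wild type 3 or Rbpj-line wild type 1 (adjusted p up to 0.0593), and Cx3cr1 and Mrc1 lost it without any 1 Rbpj-line wild type, and Mrc1 also without Psen-line wild type 1 or 2 (up to 0.0756 and 0.0825). Granular layer genes were higher (42 of 52, median 0.26, mean 0.54, adjusted p = 5.65e-07, adjusted p = 0.714 with an estimated correlation). Sprr2e (at least 2.78-fold), Rptn, Lce3c (log2 difference 2.45) and Lce3b (2.50) passed over all genes and 8 members adjusted over the list alone. Without Rbpj-line wild type 3 the list's median was 0.02 (camera adjusted p = 0.0790). A second Lce3b probe differed by 0.21, and Lce3c and Lce3b each kept their calls in only 3 of the 12 leave-outs (adjusted p up to 0.193 and 0.217). Inner root sheath and hair shaft genes were lower (26 of 32, median -0.89, and -0.79 with bounds, adjusted p = 2.36e-05, adjusted p = 0.649 with an estimated correlation). Without Rbpj-line wild type 3 their median was -0.13 (camera adjusted p = 0.209). All 6 erythroid genes were higher (median 1.59, adjusted p = 1.02e-04, adjusted p = 0.398 with an estimated correlation), with Hbb-b1 at 2.54 ± 1.05 (SE), and sebaceous genes were lower (15 of 17, median -0.32, adjusted p = 2.13e-04, adjusted p = 0.0539 with an estimated correlation).

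Smaller list shifts between the wild types all ended with single arrays left out. Skeletal muscle genes were higher (16 of 17, median 0.43, adjusted p = 0.00168, adjusted p = 0.714 with an estimated correlation), with an adjusted p of 0.0928 without Rbpj-line wild type 3 and a median of -0.05 (0.883) without Psen-line wild type 3. Interferon response genes were lower (10 of 15, median -0.25, and -0.19 with bounds, adjusted p = 0.0231, adjusted p = 0.360 with an estimated correlation). Their adjusted p was 0.0598, 0.0644 and 0.103 without Psen-line wild type 2, Psen-line wild type 3 and Rbpj-line wild type 3, and 0.0671 with a stricter detection filter. Mast cell and granulocyte genes were higher (6 of 7, median 0.95, and 0.35 with bounds, adjusted p = 0.0309, adjusted p = 0.635 with an estimated correlation), with adjusted p of 0.760, 0.0723 and 0.0928 without Psen-line wild type 3, Rbpj-line wild type 2 and Rbpj-line wild type 3, 0.137 with the stricter filter and 0.0679 with array weights. No member of these 3 lists, or of the hair shaft, erythroid and sebaceous lists, passed over all genes or adjusted over the list alone. In all, 8 lists passed and 0 did with an estimated correlation, while another split of the same 6 arrays gave 13. The unadjusted fry p was 0.000685 for macrophage, 0.00153 for sebaceous and 0.0497 for interferon response genes. It was 0.0889 for erythroid, 0.185 for hair shaft, 0.209 for mast cell and granulocyte, 0.218 for granular and 0.336 for skeletal muscle genes. The basal keratinocyte list did not differ past the threshold (median -0.07, adjusted p = 0.253), and Notch target genes had a median of -0.02 with the test direction up (adjusted p = 0.975).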

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

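Of the tests in this part, those of RNA mixing and of a wrong label for Rbpj-null 3, its second Psen1 probe and the share of genes that rose, of line, a broad array batch, and probe variants in immune and other genes for the wild-type genes, and of basal cell share and scaling for the basal list were chosen after the result was seen.

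In 3 gene lists the Psen-null effect differed from the Rbpj-null effect by the test of the difference itself at the preset correlation, and 0 of the 3 passed with an estimated one (adjusted p = 0.714 for endothelium, 0.360 for interferon response and 0.537 for skeletal muscle). Endothelium genes differed by a median of -0.41 log2 units, and the list mean per array was 0.22 ± 0.73 (SD, n = 3) in the Psen-line wild type. Relabelling arrays within the lines gave an exact permutation p of 0.485 over 400 labelings, with 0.005 the smallest possible. Interferon response genes differed by a median of -0.17 (exact permutation p = 0.08), with list means of -0.26 ± 0.01 in Psen-null and -0.12 ± 0.11 in Psen-line wild-type epidermis, and 0.23 ± 0.17 in Rbpj-null and 0.15 ± 0.05 in Rbpj-line wild-type epidermis. Skeletal muscle genes differed by a median of -1.07 (exact permutation p = 0.28), with list means from -1.23 to 1.38 among the Psen-line wild types.

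Rbpj-null 3 stood apart from the other arrays, and its Psen1 signal lay below that of the other Rbpj-null arrays (a value of -0.98 log2 units, and -1.10 for a second probe). Psen-null RNA in this sample would have to make up a share of 0.781 to give that signal, but over 27 genes that separate the lines the median share was -0.0105 (SE 0.051), which argues against mixing. A Psen-null sample under this label is argued against by the same genes, of which only 2 lay nearer to the Psen-null level. A low signal of this array stays open: 7.40% of 1499 genes of a similar level fell and 2.74% rose by as much, so the drop lay within the spread of this array, and a median change of 0.04, which quantile normalization holds near 0, decides nothing. A lower Psen1 level in the sample was not tested, nor was why the granular and spinous lists were low on this array, and no biological explanation was tested.

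The genes that differed between the wild types could follow the line, a broad array batch or sequence variants under the probes. Between the nulls, which share no array with the wild types, 98.5% of the 67 called genes outside the macrophage list, among them further myeloid genes such as Aif1, Mpeg1 and Fcrls, had the same direction, and the median ratio of the null difference to the wild-type difference was 0.908, with 45 of the 71 genes also called there. Of 22 genes with another detected probe (median ratio of its difference to the called one 0.828, SE 0.059), a variant under the probe is argued against as a set for the 9 of immune cells (0.925, SE 0.044), on which that value rests. It stays open for the other 13 as a set (0.681, SE 0.153). Their ratios ran from -0.10 for Lrp6, where the other probe had the opposite sign, to 1.20 for Ccl27a, so the median does not describe each gene. A variant also stays open for Cd33, where the other probe had the opposite sign too, and for 49 genes with no other detected probe. A batch that shifted genes broadly stays open: the wild types did not overlap in 9.68% of genes, near the 10% by chance but within the 4.39% to 33.8% of the other 9 splits of the same arrays, of which 6 lay lower, and a difference in strain or litter and a batch effect confined to few probes were not tested.

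The basal keratinocyte list was higher in both nulls, on all 3 null arrays of each line. Quantile normalization in particular is argued against, since the lowest ratio of the list's median with median scaling in its place to the value here was 0.915. Both scalings set the arrays to a common centre, so a bias that they share was not tested. A larger share of basal cells in the sample cannot be told apart from a change within cells. The mean change of Krt5, Krt14 and Krt15 was 0.148 (SE 0.153) of the list's median, but their raw signals reached 62560, near the top of the range of the arrays, where a rise may be hidden. The loss of Notch signalling that the design names stays open as an explanation and was not tested further.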

How the results depend on the processing

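In this part only the Xist covariate, the median scaling and the estimated correlation with Rbpj-null 3 left out were chosen after the result was seen. The criterion for a moved correlation, its jackknife SE of 0.217, was also set then.

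Tslp kept its call in both nulls under 25 of 25 alternatives, Krt13 in Rbpj-null epidermis under 25, and the basal list in both nulls and the sebaceous list in Rbpj-null epidermis under 26 of 27. Over all named genes, 7795 cases were counted as unchanged. For called genes this meant the same direction and a kept call, and for the others a value within 1 SD, whatever its sign. Only genes with a call could lose it, which happened in 225 cases, so 7795 is not the number to set beside these. Among genes called in a null, the number of 25 alternatives that kept the call ran from 7 for Mslnl to 25 for Tslp. Of cases without a call, 75 gained one and 152 moved by over 1 SD. Lists kept test direction and call in 677 cases, lost the call in 119 and turned in direction in 6. No named gene with a call reversed. Psen-null calls (14) were 4 without the filter on dim probes, 6 on the arrays of the comparison alone, 46 with all wild types as 1 control and 2124 with array weights, and Rbpj-null calls (7) were 11 with each probe on its own and 2 on their own arrays. Differing genes (0) were 1 with the deposited normalized values and 121 with the nulls set against each other. Wild-type genes (71) were 35 without background correction, 38 without the filter and 21 on their own arrays. Genes called in both nulls (5) were 2 without the filter, 1 on the arrays of the comparison alone, 8 with 1 control, 10 with weights and 3 with the Xist covariate. The correlation (0.523) was 0.150 with weights. With 1 control it was 0.350 (covariance 0.0478), where shared controls alone gave 0.335 (covariance 0.0218) in 100 simulations. The simulated arrays held no difference between the lines, which the real ones do. The simulated values are therefore not the matching values without an effect, and nothing is concluded from them. Lists past the threshold with an estimated correlation were 1 of 10 in Psen-null, 2 of 9 in Rbpj-null epidermis, 0 of 3 for the difference and 0 of 8 between wild types, and with Rbpj-null 3 left out too 0 in all 4 (adjusted p = 0.0661 for basal, and the spinous median of -0.038 turned in direction in Rbpj-null epidermis, 0.911). Those for the difference were 5 with the mean of all probes, 6 with median scaling and 10 with each probe on its own, with 1 control or with the nulls set against each other. Fewer arrays in the fit leave fewer degrees of freedom, and tests without the filter are adjusted over more genes. For the other changes the cause was not tested.

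Leaving out 1 array gave 2 to 31 Psen-null calls, 2 to 8 Rbpj-null calls, 0 to 1 differing genes, 18 to 98 wild-type genes, 1 to 7 shared genes and correlations of 0.331 to 0.548. Lists past the threshold ranged from 8 to 12, 8 to 13, 2 to 8 and 6 to 12. Medians ranged from -0.91 to 0.25 for the hair shaft list and from -0.59 to -0.038 for the spinous list in Rbpj-null epidermis, from -0.60 to -0.11 for endothelium in the difference, and from -0.052 to 1.17 for muscle between wild types. The test direction turned at the end of each range nearest to or past 0 (adjusted p = 0.209, 0.845, 0.850 and 0.883). Macrophage genes in Rbpj-null epidermis turned to a median of 0.16 with 1 control (adjusted p = 0.773, with 6.71e-07 to 0.773 over the alternatives). The adjusted p over all alternatives ran from 7.92e-08 to 0.915 for hair shaft, 0.00021 to 0.911 for spinous, 0.00275 to 0.850 for endothelium and 6.57e-10 to 0.883 for muscle. Signal over background limits genes near the detection limit, such as Ppp2r2b and Mslnl, whose calls held under 12 and 7 of 25 alternatives.

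The replicate numbers were not taken to pair the arrays, since not every pair of deviations correlated above 0.1. Deviations of same-numbered arrays correlated at 0.31, -0.10 and 0.42 in the Psen line and 0.08, 0.15 and 0.15 in the Rbpj line, and 8 of the 12 arrays correlated best with their own number (4 by chance). In all 4 groups replicate 1 was lowest and replicate 3 highest on the first principal component, a hint from the data that numbers share something. The main model has no term for this order, so its p-values do not account for it. With a replicate block 17 genes were called in Psen-null and 4 in Rbpj-null epidermis, 60 between wild types and 2 in both nulls. Of the main calls, 10 of 14 in Psen-null, 4 of 7 in Rbpj-null epidermis and 50 of 71 between wild types were kept. Igfbp3, Sprr2g, Krt32 and Rhov lost theirs in Psen-null epidermis, and Sprr2g, Tubb6 and Mslnl in Rbpj-null epidermis. The series matrix and a chip block were not run, the first being identical to a table used and the second having no chip named, and no wild-type comparison is possible with the wild types pooled.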

Other observations

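The calls without Rbpj-null 3, its additional genes, and the comparison of near-threshold genes were chosen after the result was seen. The splits of the arrays were set before.

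Without Rbpj-null 3, 31 genes were called in Psen-null epidermis, the 14 described in the report among them. Il1b, a cytokine of keratinocyte stress, rose 2.87-fold (limma adjusted p = 0.0354), and Ascl2, a transcription factor, 2.88-fold (0.0478). Klk1b9, a kallikrein, rose from a signal undetected on all 3 wild-type arrays (0.0478). Antxr1 and Il17rd, a regulator of growth factor signalling, rose 1.86-fold and 1.94-fold (both 0.0354). Oas1f fell 3.28-fold (0.0404), Nupr1 2.65-fold (0.0478) and the monoamine oxidase gene Maob 2.47-fold (0.0354). In Rbpj-null epidermis 8 genes were called without that array, 5 of the 7 in the report among them, and Igfbp3 rose 10.49-fold (0.0148) and the monooxygenase gene Fmo3 rose from an undetected wild type (0.0465). Leaving this array out changes the estimate of the spread for every comparison, and genes of the Psen line have the same fold changes as with it.

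A hypothesis is that the nulls share part of their transcriptional change. Over the 100 combinations of a split of the arrays in each line, 4 gave a correlation of fold changes as far from 0 as the real one of 0.523, and the highest other was 0.567. That share lay under the 0.05 set beforehand, but it does not exclude chance. The combinations weigh the same only if the arrays of a line are interchangeable. The order of the replicates on the first principal component is a hint that they are not. For the 5 genes called in both, chance was not decided either. Only the real combination gave 5 (1 of 100, with 0 the highest other). Every other combination called at most 1 gene in at least 1 of the lines, so none could share 5. The combination with the higher correlation set Psen-null 1, Psen-null 2 and Psen-line wild type 1 against the rest of their line, and Rbpj-null 1, Rbpj-null 2 and Rbpj-line wild type 3 against theirs, so a structure of the arrays other than the genotype could give a correlation of this size. A shared change is consistent with the correlation.

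For single comparisons the splits of 6 arrays into 3 and 3 are too few for a share under 0.05. As many genes as the real 14 in Psen-null epidermis came from 1 of 10 splits, the real one, with 1 gene in the highest other. The values were 1 of 10 for the 7 Rbpj-null genes (highest other 1) and 1 of 10 for the 71 genes between wild types (highest other 1). For lists past the threshold, 3 of 10 splits gave as many as the 10 in Psen-null epidermis (highest other 12), 2 of 10 as many as the 9 in Rbpj-null epidermis (highest other 10), and 5 of 10 as many as the 8 between wild types (highest other 13). For the difference between the nulls 0 genes were found, so all labelings (100 of 100 drawn, highest other 2) gave as many and the count decides nothing about chance. For its 3 lists chance was not excluded, as 97 of 100 gave as many (highest other 14).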
